A study of Mus musculus with 16 samples.

How the data were processed

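The samples were immortalized preadipocytes of the wild-type mouse strain C57Bl6/J, a line of fat cell precursors that can be induced to form adipocytes in culture. Cells had been given interleukin-13 (IL-13) for 16 h beforehand or had been left untreated, and were taken at day 0 or day 6 of differentiation. Per the labels, RNA was purified on spin columns, and 2 ug of total RNA went into each library of Illumina's stranded mRNA kit, which selects polyadenylated transcripts. The labels gave 16 libraries in 4 groups of 4, and each group carried replicate numbers 1 to 4. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

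The values came from 2 tables, for day 0 and for day 6, each with 41325 genes. Per the file headers, the authors gave for every library a total read count per gene, which held whole numbers with no normalization. The authors also deposited RPKM and TPM values, which scale the counts to transcript length and library size, and these were not used here beyond checking what they held. The authors' deposited CPM column was treated as a score, because per the file headers it rests on an adjusted library size, and the adjustment factors implied by its sums multiplied to 1 within each table. The other deposited columns held the authors' own comparisons. The genome build named in the submitters' processing notes was mm10; the aligner, the counting tool, their versions, the gene annotation and whether counting used the strand are not given in the sources used here. The gene coordinates in the tables were those of GRCm38, and 41297 of the 41325 gene identifiers were found in the GENCODE annotation used here, 40833 of them with the same symbol. All columns of values were assigned to a library by name.

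Library totals lay between 15253031 and 18112087 counts. Counting error thus weighs on genes near or under about 1 CPM (a count scaled to library size) and is smaller at higher levels. All fold limits for a group without any count were computed against 3 counts over the group's 4 libraries. Those limits cover counting error only, because reads copied during amplification are not independent molecules. No pair of libraries within a group agreed within sampling noise, so all 16 were kept.

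Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation, trimmed mean of M values (TMM) scaling, and edgeR's expression filter at its defaults (a minimum count of 10 and a minimum total of 15). The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The IL-13 comparisons at day 0 and at day 6 each used their own 8 libraries; the day comparisons and the difference of the IL-13 effect between the days used all 16. Log2 fold changes are IL-13 over untreated or day 6 over day 0, and their standard error (SE) is the fold change divided by the square root of the test's F statistic. Levels are CPM on the TMM-scaled library sizes of the comparison, given as mean ± SD over the 4 libraries of a group.

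Before the data were examined, 24 gene lists were fixed with 448 entries (434 distinct genes), for adipocyte biology, IL-4 and IL-13 signalling, metabolism, matrix, stress and inflammation, and for markers of other cell types. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. Camera used a preset correlation of 0.01, and again an estimated correlation. Beside it the lists were tested with fry of limma, which judges each list without comparing it to other genes. List p-values were adjusted together over the comparisons within days and, separately, over the other 3 comparisons. The genes the text names were also chosen by a rule fixed then. It took, for each IL-13 comparison and for day 6 against day 0 in untreated cells, the 10 genes with the largest fold in each direction among called genes with a mean log2 CPM of at least 1, no overlap between the groups' libraries and a proper gene name. It added up to 4 members of each list with the smallest p, a fixed panel of IL-13 pathway and adipocyte genes, and for the difference between the days the 5 genes with the smallest adjusted p in each direction. Genes named only to complete a count of 5 or fewer, and the genes of the chromosomal clusters, were chosen after their values were seen. Some genes that the rule named are not reported here.

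An index of nuclear RNA was added after the data had been examined, because Neat1 and Malat1, long RNAs that stay in the nucleus, were among the genes with the largest falls. It was the mean log2 CPM of 23 other nuclear-retained RNAs and transcripts of splicing and RNA-processing factors, written from background knowledge after the falls of Malat1, Neat1, Firre, Dnm3os, Rsrp1 and Ccnl2 had been seen and leaving those genes out, of which 22 passed the filter on each day.

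The alternatives were DESeq2 1.42.0, limma voom, 3 other scalings, no filter and a stricter filter, a test against a fold change of 1.5 (glmTreat), a block for the replicate number, each library left out in turn, and fits with more or fewer libraries. The alternatives chosen after seeing the data were the nuclear RNA index as a covariate, offsets for transcript length and GC content fitted with mgcv 1.9.3, and fits without the untreated libraries with most nuclear RNA. The replicate numbers were checked for pairing on the 2000 most expressed genes. Deviations from the group means of libraries with the same number correlated at 0.135 to 0.628 in all 4 pairs at day 6. Libraries with different numbers correlated at up to 0.712 there. At day 6, 4 of 8 libraries correlated best with their own number, against 6 of 8 at day 0. Pairing at day 6 was thus assumed, because all 4 pairs were above 0.1, rather than shown. The blocked count of called genes is given beside the day 6 count. Day 6 values of single genes are from the fit without the block. At day 0 and across the days at least 1 pair correlated at 0.1 or less.

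The tests were run first on simulated data with 200 changed genes. In the simulated day 0 comparison, over 12274 genes, 77.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 92.4% of those changed 4-fold were called, and 6.91% of the calls were false. At day 6, over 12352 genes, these shares were 76.1%, 97.0%, 95.5% and 5.29%. For the difference between the days, over 13157 genes, they were 56.7%, 73.1%, 95.5% and 6.83%. These simulations drew genes independently, without a trend shared across libraries, so their shares of false calls need not hold for these data. In another day 6 simulation, a trend on transcript length was planted in the IL-13 libraries. It gave 1437 false calls beside 186 true ones, and 10 beside 182 with offsets for transcript length and GC content.

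The authors' deposited tables gave a log fold change and a false discovery rate (FDR) for 19224 genes at day 0 and 19196 at day 6. Their fold changes had the opposite sign to those computed here for 100% of the genes called here (correlation across genes -0.999989 at day 0 and -0.999964 at day 6), so the authors' deposited table sets untreated over IL-13. It lists 4740 genes at day 0 and 726 at day 6 with an FDR under 0.05, of which 4582 and 535 were also called here.

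Some counts carry a further uncertainty. Because the counting is not stated to use the strand, reads of a gene and of a gene on the opposite strand may have been pooled. Among the genes named with values, Akr1b7, Ccnd1, Cish, Cox5a, Csf1r, Daglb, Fbn1, Hmgcs1, Ptger4, Tgm2, Timp3 and Uqcrc2 shared between 11.5% and 27.2% of their exon bases with genes on the opposite strand.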

Results

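The data are counts of polyadenylated RNA per gene in immortalized mouse preadipocytes, fat cell precursors that become adipocytes in culture once differentiation is induced. The cells had or had not been given IL-13, a type 2 immune cytokine that acts through the receptor subunit Il4ra and the transcription factor Stat6, for 16 h. They were taken at day 0 or day 6 of differentiation, which gave 4 groups of 4 libraries: untreated and IL-13 pre-treated at day 0, and untreated and IL-13 pre-treated at day 6. Library totals ran from 15253031 to 18112087 counts, and between 15447 and 16201 genes had at least 1 count. The design allows 3 questions, namely which transcripts IL-13 changed before differentiation, which differences were seen at day 6, and how cells with and without pre-treatment changed over the 6 days. Coordinates are those of GRCm38 (mm10), and levels are CPM as mean ± SD over n = 4 libraries.

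At day 0, IL-13 pre-treated cells held far more transcripts of several serine protease inhibitors and chemokines than untreated cells. Serpinb1a (ENSMUSG00000044734, chromosome 13, 32842092 to 32851185), an inhibitor of neutrophil proteases, rose from 2.01 ± 0.576 to 277 ± 18.2 CPM (log2 fold change 7.12, SE 0.11, adjusted p = 1.52e-15). Serpina3g (ENSMUSG00000041481, chromosome 12, 104236245 to 104241939) rose from 2.03 ± 0.454 to 247 ± 15.3 CPM (6.93, SE 0.10, adjusted p = 3.81e-16). Its neighbours Serpina3n and Serpina3c rose from 0.223 ± 0.143 to 23.5 ± 2.65 CPM and from 0.330 ± 0.126 to 22.0 ± 1.16 CPM. Of the 50-base stretches of these 4 transcripts, between 3.42% and 16.0% also occur in transcripts of other genes, so part of their counts could have been shared with relatives. Ccl11 (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955), the eosinophil attractant eotaxin, rose from 0.0863 ± 0.0329 to 17.5 ± 2.20 CPM (7.54, SE 0.22, adjusted p = 6.23e-13). Among the genes chosen by the rule, Diras2, Myocd, Crispld2, Hlf, Aif1l and Pcolce2 followed with increases between 13.5-fold for Pcolce2, a procollagen processing enhancer, and 23.2-fold for Diras2, a small GTPase.

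Among the genes chosen by the rule, the 10 with the largest falls at day 0 were Dnm3os, Dock10, Neat1, Slc40a1, Adcyap1r1, BC005561, Clec2d, Fat4, Rspo2 and Malat1, from a log2 fold change of -2.69 (SE 0.41) for Dnm3os to a 3.89-fold lower level of Malat1. Slc40a1, the cellular iron exporter, fell from 23.5 ± 4.34 to 5.18 ± 1.49 CPM. Rspo2, an activator of Wnt signalling, had a log2 fold change of -2.03 (SE 0.07). Neat1 (ENSMUSG00000092274, chromosome 19, 5824708 to 5845478) and Malat1, long RNAs retained in the nucleus, fell from 69.2 ± 32.0 to 14.1 ± 2.48 CPM and from 179 ± 72.3 to 46.0 ± 11.3 CPM. Their levels spread widely among the untreated libraries, with Neat1 between 31.2 and 103 CPM. The nuclear RNA index, from 22 other RNAs of this kind, was 6.36 ± 0.226 log2 CPM in untreated and 5.87 ± 0.0491 in IL-13 libraries (exact permutation p = 0.0286, two-sided, the smallest that 70 permutations can give). Of those 22 RNAs, 17 fell and 5 did not pass the test.

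Genes of the IL-13 pathway itself moved in the same cells. Of the 10 tested members of the IL-4 and IL-13 response list, 7 rose and 2 fell, Egr2 and Vcam1 (adjusted over the list alone, also 7 and 2; camera adjusted p = 0.00291; adjusted p = 0.287 with an estimated correlation). Cish, a feedback inhibitor of cytokine receptors, rose from 10.7 ± 1.01 to 73.4 ± 4.13 CPM (log2 fold change 2.78, SE 0.07), and Tgm2, a transglutaminase, from 32.6 ± 2.75 to 106 ± 3.03 CPM. Il4ra (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474) rose from 33.4 ± 2.08 to 87.9 ± 3.14 CPM (1.40, SE 0.06, adjusted p = 4.08e-11), and Socs1, another feedback inhibitor, from 0.636 ± 0.167 to 2.77 ± 0.574 CPM. In the list of IL-4 and IL-13 receptors and their kinases 2 of 10 rose and 3 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.765). The receptor subunit Il13ra1 fell by 0.39 on the log2 scale (SE 0.10), and Stat6 was at 178 ± 5.34 and 183 ± 6.13 CPM (log2 fold change 0.04, SE 0.05, adjusted p = 0.541). The decoy receptor Il13ra2, below the filter for testing, had 0 counts in the untreated libraries and 30 in the IL-13 libraries, at least 10.9-fold higher when the untreated group is set to 3 counts.

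Matrix and inflammatory genes also differed at day 0. In the extracellular matrix list 15 of 25 tested genes rose and 3 fell, likewise when adjusted over the list alone (camera adjusted p = 0.00334; adjusted p = 0.682 with an estimated correlation). Col6a2 and Col6a1, chains of type VI collagen, rose from 1171 ± 128 to 4966 ± 247 CPM and from 2103 ± 207 to 7065 ± 257 CPM. Fbn1 (fibrillin 1) rose 2.46-fold. The chemokines Ccl2 and Ccl7, which attract monocytes, rose 10.2-fold and 8.42-fold. Of the inflammatory list 3 of 9 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.697). In the interferon response list 0 of 17 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00136; adjusted p = 0.287 with an estimated correlation). Ifit2 fell from 66.8 ± 3.95 to 40.7 ± 2.85 CPM and Ifit3, like it an antiviral interferon target, from 16.5 ± 1.38 to 6.73 ± 1.65 CPM.

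Lists of mitochondrial energy metabolism, protein stress and cholesterol synthesis were called at day 0 as well. In the oxidative phosphorylation list 21 of 24 genes rose and 0 fell (22 and 1 adjusted over the list alone; camera adjusted p = 1.26e-05; adjusted p = 0.682 with an estimated correlation). Ndufb8 of complex I was at log2 fold change 0.43 (SE 0.06) and Sdhb of complex II at 0.40 (SE 0.06). In the fatty acid oxidation list 11 of 19 rose and 1 fell, Cpt1b (12 and 1 adjusted over the list alone; camera adjusted p = 0.0192; adjusted p = 0.583 with an estimated correlation). Among its members Etfb changed by 0.39 (SE 0.07), although 58.2% of its exon bases also belong to another gene on the same strand, and Acaa2 by 0.41 (SE 0.07). In the unfolded protein and amino acid stress list 11 of 17 rose and 2 fell, Ddit4 and Atf4, also when adjusted over the list alone (camera adjusted p = 0.0192; adjusted p = 0.287 with an estimated correlation). Xbp1, a transcription factor of that response, rose 1.58-fold and Chac1 1.65-fold. In the cholesterol synthesis list 2 of 20 rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.00648; adjusted p = 0.287 with an estimated correlation). Its enzymes Hsd17b7 and Hmgcs1 fell by 0.72 (SE 0.05) and 0.61 (SE 0.06) on the log2 scale, and the sterol sensor Insig1 fell by 0.62 (SE 0.07). These changes, all under 2-fold among the called members except Cpt1b (-1.25, SE 0.33), were measured between libraries that also differed in the nuclear RNA index.

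Fat cell genes were mixed at day 0. Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399), the nuclear receptor that drives fat cell formation, rose from 64.7 ± 1.42 to 95.4 ± 5.74 CPM (log2 fold change 0.56, SE 0.05, adjusted p = 9.66e-07), while its partner Cebpa fell from 24.0 ± 1.08 to 16.9 ± 0.778 CPM (-0.50, SE 0.07, adjusted p = 4.93e-05). Fabp4, a fatty acid carrier, was at 112 ± 8.16 and 105 ± 3.57 CPM (-0.10, SE 0.06, adjusted p = 0.176). In the mature adipocyte list 6 of 13 tested genes rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.221). The triglyceride lipase Pnpla2 rose 1.95-fold, and those that fell were Cebpa and the lipoprotein lipase Lpl (-0.33, SE 0.05). Of 16 preadipocyte genes 5 rose and 1 fell, Cd24a (4 and 1 adjusted over the list alone; camera adjusted p = 0.467). Among the 5 that rose, Ly6a went from 48.7 ± 4.31 to 93.4 ± 9.83 CPM, Cd34 from 0.738 ± 0.225 to 2.94 ± 0.745 CPM and Pi16 from 0.498 ± 0.180 to 1.45 ± 0.631 CPM. Of 13 early adipogenic regulators 4 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.914). Klf4 rose from 31.5 ± 1.32 to 111 ± 3.66 CPM. In the thermogenic list 2 of 8 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.963). Tmem26, a surface marker of beige adipocytes, rose from 12.7 ± 1.60 to 128 ± 7.53 CPM, and the pyruvate dehydrogenase kinase Pdk4 fell from 44.4 ± 2.25 to 24.3 ± 1.71 CPM.

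In all, 5881 of 12274 tested genes were called at day 0, 2912 higher and 2969 lower. Of these, 253 and 267 differed by 2-fold or more, and 88 and 28 by 4-fold or more. Scaling by total count only gave 1682 higher and 4523 lower and moved the median log2 fold change of all genes to -0.13. Without untreated libraries 1 and 4, which held most nuclear RNA, 3485 genes were called. With the nuclear RNA index as a covariate 808 genes were called. Of the 253 genes raised 2-fold or more 177 kept their call, with a median log2 fold change of 1.60 before (median SE 0.14) and 1.56 after (0.31). Of 263 lowered 2-fold or more outside the nuclear RNA list 88 did, with -1.24 before (median SE 0.23) and -0.96 after (0.36). Of the genes changed under 2-fold, also outside that list, 221 of 2659 raised and 281 of 2689 lowered kept their call, and their medians went from 0.31 to 0.15 and from -0.37 to -0.17.

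**Figure D1:**
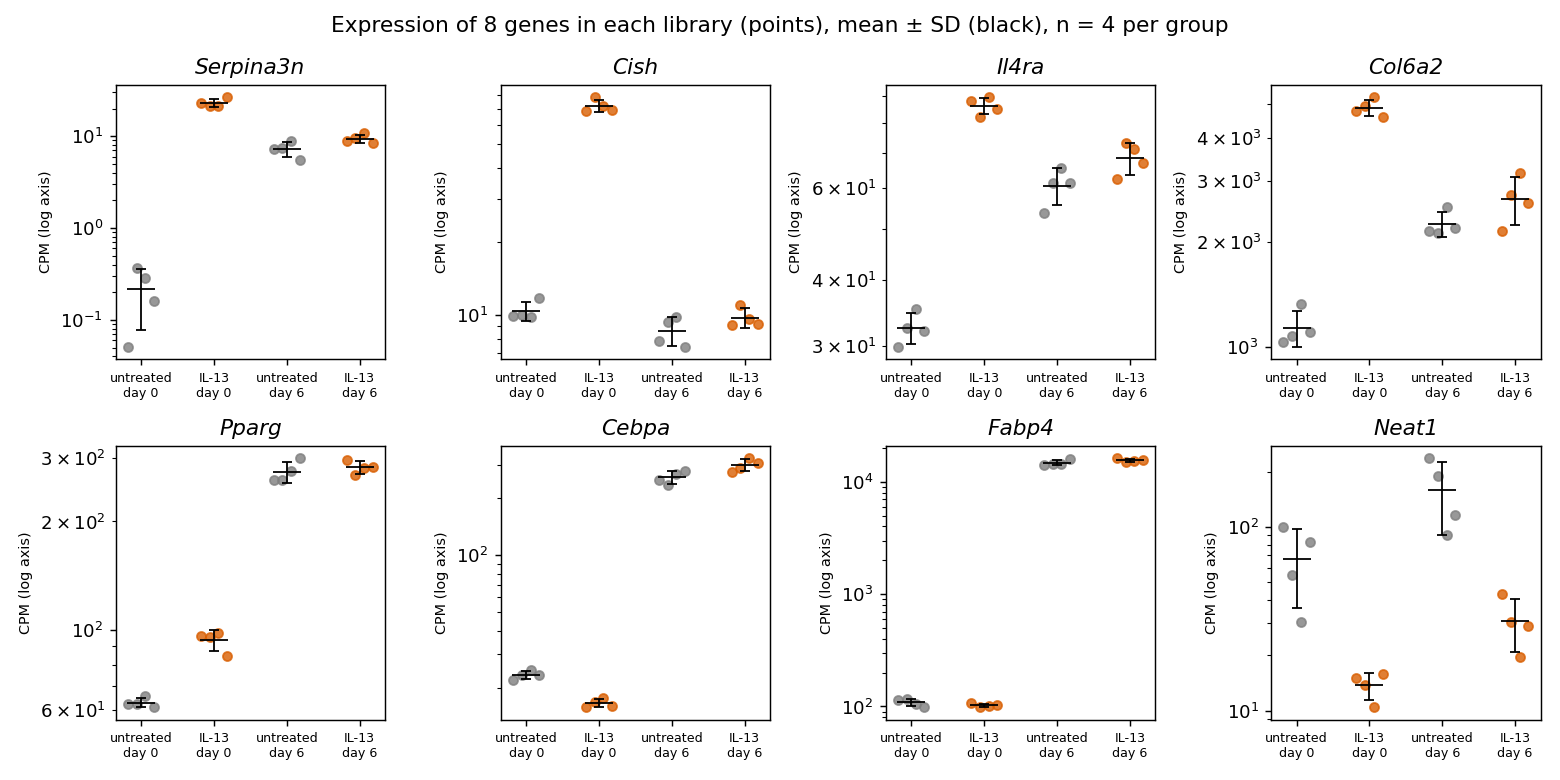
CPM of 8 genes in each of the 16 libraries (points) on a log axis, scaled across all libraries, with the mean and SD of each group of 4 in black; grey marks untreated and orange IL-13 pre-treated cells. Serpina3n, Cish, Il4ra and Col6a2 stand apart between the groups at day 0, Fabp4 and Cebpa between the days, and Neat1 is lower in IL-13 libraries on both days.

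At day 6, the increases in IL-13 pre-treated over untreated cells were all under 2-fold among the called genes, while some nuclear long RNAs were over 4-fold lower. The largest increases among the genes chosen by the rule were Cd74 (7.18 ± 1.10 to 14.0 ± 2.85 CPM; log2 fold change 0.96, SE 0.16, adjusted p = 0.0115), the invariant chain of antigen presentation, Crtac1 (0.93, SE 0.21), Aif1l (0.69, SE 0.11), Akr1b7 (0.68, SE 0.13), Lars2 (0.68, SE 0.08) and Pcolce2 (0.67, SE 0.15). The largest falls among the genes chosen by the rule were in Firre (ENSMUSG00000085396, chromosome X, 50555744 to 50635321; 18.3 ± 8.58 to 2.80 ± 1.12 CPM; -2.69, SE 0.41, adjusted p = 0.0146) and Neat1 (153 ± 64.9 to 30.0 ± 9.33 CPM; -2.35, SE 0.37), both nuclear long RNAs. Next among them came Rsrp1 (-2.27, SE 0.32), Lgals4 (-2.02, SE 0.27) and Dnm3os (-1.98, SE 0.33). The nuclear RNA index was again lower after IL-13, 6.08 ± 0.205 against 6.71 ± 0.199 log2 CPM (exact permutation p = 0.0286, two-sided, the smallest that 70 permutations can give). Within the replicate pairs it was lower in 4 of 4, where an exact sign-flip test gave p = 0.125, two-sided, the smallest that 16 sign flips can give. Of its 22 RNAs 16 fell and 6 did not pass.

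Fat cell genes differed little at day 6. In the mature adipocyte list 3 of 24 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00327; adjusted p = 0.682 with an estimated correlation). They were Agpat2, a triglyceride synthesis enzyme (0.39, SE 0.09), Aoc3 (0.31, SE 0.07) and Adipoq, the hormone adiponectin. Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) was at 1352 ± 74.5 and 1660 ± 137 CPM (0.30, SE 0.07, adjusted p = 0.0345). Cd36 (0.21, SE 0.06, adjusted p = 0.0528), Pparg (0.06, SE 0.06, adjusted p = 0.576), Cebpa (0.22, SE 0.07, adjusted p = 0.0804), Fabp4 (0.08, SE 0.06, adjusted p = 0.449) and Plin1 (0.18, SE 0.07, adjusted p = 0.139) did not pass the test without the replicate block. With the block more genes were called at day 6, so genes near the threshold depend on it. Ucp1, the uncoupling protein of brown and beige fat, was at 32.3 ± 7.32 and 42.3 ± 10.3 CPM (0.39, SE 0.19, adjusted p = 0.219). Of 16 thermogenic genes 1 rose, Elovl3 (0.32, SE 0.07), with 0 falls (1 and 0 adjusted over the list alone; camera adjusted p = 0.610). In the fatty acid and triglyceride synthesis list 3 of 20 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0698). The falling gene was Mlxipl, the carbohydrate response factor ChREBP, from 104 ± 21.7 to 56.5 ± 7.81 CPM (-0.88, SE 0.14).

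In the oxidative phosphorylation list 3 of 24 genes rose and 0 fell at day 6, Ndufb8 (0.29, SE 0.07), Atp5c1 and Cox5a (0.25, SE 0.07), against 14 and 1 adjusted over the list alone (camera adjusted p = 1.26e-05; adjusted p = 0.682 with an estimated correlation). In the fatty acid oxidation list 3 of 20 rose, Acaa2 (0.27, SE 0.07), Decr1 (0.26, SE 0.06) and Cpt1a, and 0 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.298). The glycolysis list was called as higher although none of its 18 genes passed singly in edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.0192; adjusted p = 0.782 with an estimated correlation). Its leading gene Tpi1 had a log2 fold change of 0.31 (SE 0.09, adjusted p = 0.0546). In the unfolded protein and amino acid stress list 2 of 18 rose, Pdia4 (0.28, SE 0.07) and Psat1 (0.22, SE 0.06), and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0192; adjusted p = 0.682 with an estimated correlation). All 4 lists called at day 6 were measured between libraries that also differed in the nuclear RNA index. With that index as a covariate some named members changed sign. These were Agpat2 (-0.0170), Cebpa (-0.0330) and Plin1 (-0.0422) of the mature adipocyte list, Ndufb8 (-0.0283), Tpi1 (-0.12) and Pdia4 (-0.0284). Other named members, such as Pparg and Fabp4, did not change sign with the covariate. Acaa2, of the fatty acid oxidation list that was not called, turned to -0.0231. Without the replicate block, the IL-4 and IL-13 response list had no call by edgeR among its 12 tested members, over all genes or adjusted over the list alone (camera adjusted p = 0.839). Il4ra was at 58.8 ± 4.87 and 67.1 ± 5.11 CPM (0.19, SE 0.08, adjusted p = 0.136) and Ccl11 at 1.09 ± 0.363 and 0.968 ± 0.559 CPM (-0.16, SE 0.38, adjusted p = 0.825).

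In total 809 of 12352 genes were called at day 6, 273 higher and 536 lower, of which 0 were higher and 122 lower by 2-fold or more. Total count scaling gave 53 higher and 1032 lower, and offsets for transcript length and GC content 1491 higher and 786 lower (2531 and 1233 with the replicate block). The replicate block, which takes the numbers as pairs, gave 2812 (1342 higher and 1470 lower). The count fell to 102, 60 or 523 without untreated library 1, 2 or 3 and to 62, 205 or 320 without IL-13 library 2, 3 or 4. It rose to 2328 without IL-13 library 1, and was 2 without untreated libraries 1 and 2, which held most nuclear RNA. With the nuclear RNA index as a covariate edgeR called 0 genes, with 872 at an unadjusted p under 0.05. On each day every IL-13 library lay below every untreated one in that index, so the covariate overlaps with IL-13. A fit with it has little power to separate the 2, and the 0 calls do not show which of them the differences come from. DESeq2 without the covariate called 1470.

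The test of the difference of the IL-13 effect between the days showed which responses had changed by day 6. The IL-4 and IL-13 response list fell in this difference (0 rose and 9 fell of 13; 1 and 9 adjusted over the list alone; camera adjusted p = 5.14e-09; adjusted p = 0.00344 with an estimated correlation). Serpina3g differed by -6.59 (SE 0.18), Aldh1a7 by -2.48 (SE 0.07), Daglb by -2.68 (SE 0.09), Aif1l by -3.26 (SE 0.13) and Enpp3 by -2.96 (SE 0.12). Of the fixed panel, Ccl11 differed by -7.72 (SE 0.52), Il4ra by -1.23 (SE 0.10) and Pparg by -0.53 (SE 0.08), while Il13ra1, Stat6, Fabp4, Adipoq, Ucp1 and Pdgfra did not pass the test. In the other direction Nrp2 differed by 1.09 (SE 0.07), Rspo2 by 2.14 (SE 0.18), Gas2 by 1.45 (SE 0.13), Mme by 1.34 (SE 0.13), Slc1a3 by 1.33 (SE 0.13) and Cebpa by 0.70 (SE 0.10). The cholesterol synthesis list rose in the difference (8 of 20 rose and 0 fell; 11 and 0 adjusted over the list alone; camera adjusted p = 3.70e-08; adjusted p = 0.00541 with an estimated correlation), that is, its falls at day 0 had lessened by day 6. The interferon list also rose (5 of 18 and 0 fell, also when adjusted over the list alone; camera adjusted p = 3.68e-05; adjusted p = 0.125 with an estimated correlation). The matrix list fell (1 rose and 7 fell of 26; 2 and 8 adjusted over the list alone; camera adjusted p = 0.00543; adjusted p = 0.402 with an estimated correlation), as did oxidative phosphorylation, with no single call by edgeR among 24 genes (camera adjusted p = 0.0190; adjusted p = 0.641 with an estimated correlation). Of the 46 genes raised 4-fold or more at day 0 and tested on both days, the median log2 fold change was 2.77 at day 0 and 0.16 at day 6. Of these, 4 were still called higher at day 6, Aif1l, Aldh1a7, Ezr and Pcolce2.

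The difference was called for 1061 of 13157 genes, 410 higher and 651 lower. This split became 509 and 505 with RLE scaling, 516 and 498 with total count only, 507 and 530 with upper quartile scaling, and 725 and 657 with the offsets for length and GC content. Without the 4 untreated libraries that held most nuclear RNA 545 genes were called, and with the index as a covariate 2132. The replicate block gave 1608 and a block within each day 1787. Across days, 200 genes were called higher on both and 358 lower on both, where independent lists would share 63.9 and 119. Another 4 and 6 were called in opposite directions. The nuclear RNA index was lower in IL-13 libraries on both days, which could also give shared calls. The overlap thus does not show that effects of IL-13 lasted.

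**Figure D2:**
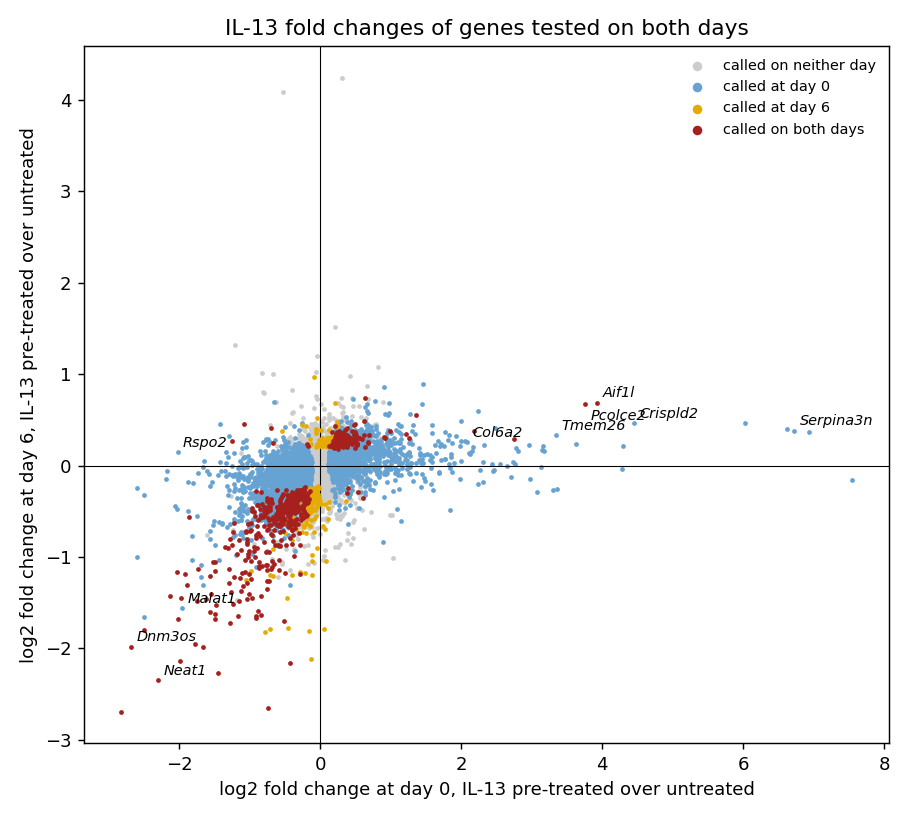
Log2 fold change of IL-13 pre-treated over untreated cells at day 0 (horizontal) and day 6 (vertical) for the 11541 genes tested on both days, coloured by the days on which each was called. Genes raised most at day 0, such as Serpina3n and Crispld2, are far less raised at day 6, while Neat1, Malat1 and Dnm3os are lower on both days.

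From day 0 to day 6, untreated cells took on the transcripts of fat cells. Cd36, the fatty acid transporter (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801), had 0 counts at day 0 and 2343 ± 84.4 CPM at day 6, and Car3, Mmd2, Lgals12 and Adig also went from 0 counts to between 217 and 1196 CPM. Against 3 counts over the group these were at least 56138-fold higher for Cd36 and at least 5196-fold for Adig. The lipid droplet gene Cidec rose by a log2 fold change of 14.24 (SE 0.19), and Adipoq went from 0.0822 ± 0.0262 to 1391 ± 74.9 CPM. All 24 tested mature adipocyte genes rose, also when adjusted over the list alone (camera adjusted p = 2.38e-13; adjusted p = 0.00186 with an estimated correlation). Plin1, the lipid droplet coat protein, had a log2 fold change of 12.24 (SE 0.14). Fabp4 rose from 109 ± 8.13 to 14817 ± 837 CPM, Pparg rose 4.37-fold and Cebpa rose by a log2 fold change of 3.47 (SE 0.07). In the thermogenic list 14 of 16 rose and 1 fell, Tmem26, also when adjusted over the list alone (camera adjusted p = 7.30e-06; adjusted p = 0.00541 with an estimated correlation). Elovl3 reached 584 ± 42.3 CPM, and Ucp1 went from 0 counts to 33.3 ± 7.48 CPM, at least 796-fold higher.

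Lipid and energy metabolism rose over the same days. In the fatty acid oxidation list 19 of 20 genes rose and 1 fell, Cpt1a, also when adjusted over the list alone (camera adjusted p = 3.06e-09; adjusted p = 0.00977 with an estimated correlation). The beta-oxidation enzyme Hadhb rose 17.6-fold. All 24 oxidative phosphorylation genes rose, also when adjusted over the list alone (camera adjusted p = 6.88e-10; adjusted p = 0.240 with an estimated correlation). Uqcrc2 and Uqcrfs1 of complex III rose 5.73-fold and 7.23-fold. In the fatty acid and triglyceride synthesis list 17 of 20 rose and 3 fell, Elovl6, Fads1 and Fads2, also when adjusted over the list alone (camera adjusted p = 3.15e-06; adjusted p = 0.0594 with an estimated correlation). Acacb rose 62.9-fold and Scd1, the stearoyl-CoA desaturase, from 547 ± 43.8 to 21333 ± 846 CPM. The glycolysis list (16 of 18 rose and 1 fell; camera adjusted p = 8.20e-05; adjusted p = 0.348 with an estimated correlation), with Pfkfb3 at 30.8-fold, was called as higher. So were the early adipogenic regulators (12 of 15 rose and 1 fell, Klf4; camera adjusted p = 0.00659; adjusted p = 0.0850 with an estimated correlation), with Nr1h3 (the liver X receptor) at 25.7-fold and Srebf1 at 9.70-fold. Also called as higher were the glucocorticoid and cAMP targets (14 of 15 rose and 1 fell, Sgk1; camera adjusted p = 7.70e-04; adjusted p = 0.236 with an estimated correlation), with Angptl4 at 21.1-fold and Pdk4 at 5.82-fold, and the unfolded protein and amino acid stress list (12 of 18 rose and 2 fell; camera adjusted p = 0.0347; adjusted p = 0.334 with an estimated correlation). In these 4 lists the counts were the same when adjusted over the list alone.

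Precursor, matrix and proliferation genes fell. Apob was at 46.3 ± 4.27 CPM at day 0 and had 2 counts over the day 6 group, a ratio of 1493 (95% counting interval 413 to 12335). Next among the genes chosen by the rule came Cemip, Col2a1, Actg2 and Cdh3 with log2 fold changes from -9.77 (SE 0.20) to -8.93 (SE 0.14). In the matrix list 22 of 26 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 4.90e-06; adjusted p = 0.243 with an estimated correlation). Tnc (tenascin C) fell from 412 ± 12.2 to 3.05 ± 0.540 CPM, smooth muscle actin Acta2 from 3608 ± 410 to 28.6 ± 5.45 CPM and Timp3 from 338 ± 13.2 to 26.6 ± 0.601 CPM. In the preadipocyte list 12 of 17 fell and 2 rose, Zfp423 and Fgf10, also when adjusted over the list alone (camera adjusted p = 0.00511; adjusted p = 0.125 with an estimated correlation). Cd24a and Thy1 fell by 5.34 (SE 0.10) and 4.49 (SE 0.10) on the log2 scale. Pdgfra was at 359 ± 16.2 and 347 ± 36.0 CPM (-0.05, SE 0.08, adjusted p = 0.620). In the cell cycle list 16 of 24 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.402 with an estimated correlation). Ccnd1 (cyclin D1) fell from 106 ± 7.61 to 0.675 ± 0.339 CPM, and Cdc20 was at -1.46 (SE 0.06). The IL-13 receptor subunit Il13ra1 fell from 11.5 ± 1.10 to 0.927 ± 0.0800 CPM, and Il4ra rose 1.87-fold.

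In untreated cells 10590 of 13157 genes were called between the days, 5465 higher and 5125 lower. In IL-13 pre-treated cells 10637 were called, 5337 higher and 5300 lower, and panel genes moved as follows. Adipoq rose from 0.199 ± 0.0908 to 1694 ± 134 CPM, Plin1 from 0.434 ± 0.103 to 646 ± 60.3 CPM, Fabp4 from 103 ± 3.10 to 15509 ± 521 CPM, Pparg 3.02-fold and Cebpa 17.9-fold. Il13ra1 fell from 8.88 ± 0.458 to 0.856 ± 0.281 CPM. Il4ra fell from 86.1 ± 3.21 to 68.4 ± 4.77 CPM in these cells (log2 fold change -0.33, SE 0.07), but was at 0.04 with the offsets for transcript length and GC content. In the pre-treated cells 11 lists were called between the days, 8 higher and 3 lower, of which 3 were called with an estimated correlation. The days came in separate tables, and the labels do not say whether they were handled together.

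**Figure D3:**
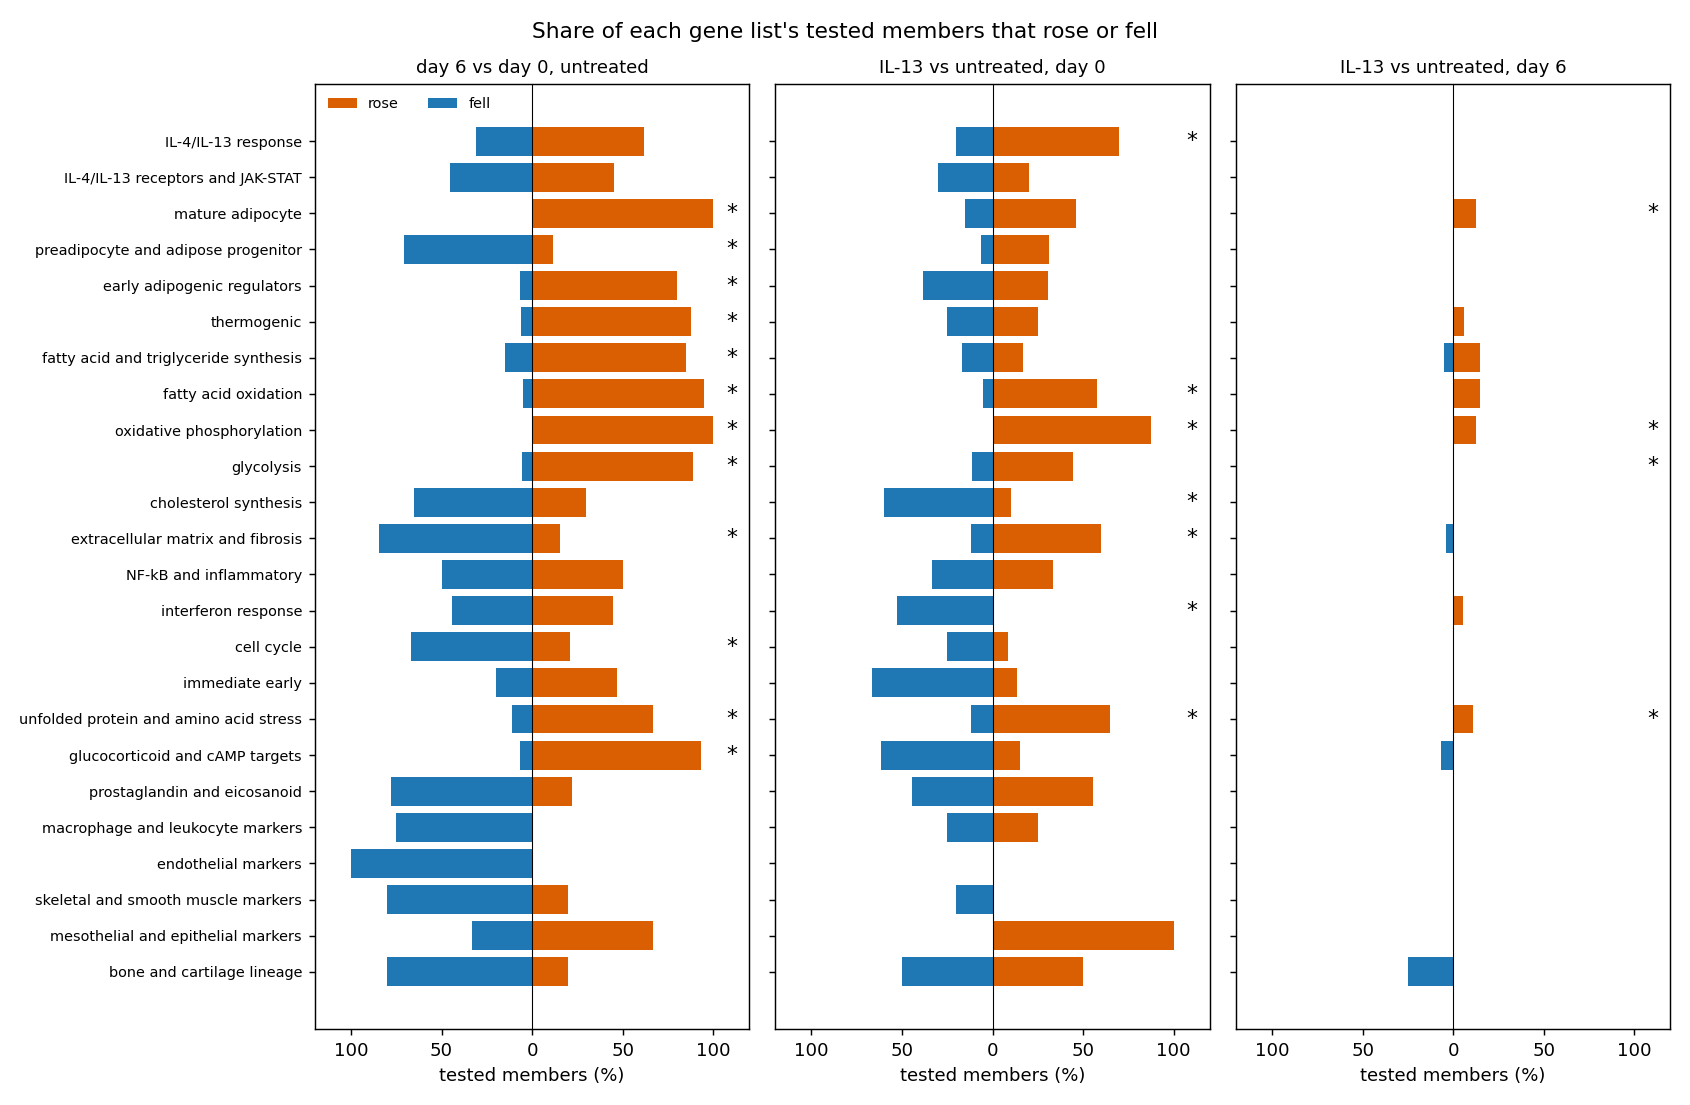
Percentage of the tested members of each of the 24 gene lists that rose (orange, to the right) or fell (blue, to the left), for day 6 over day 0 in untreated cells and for IL-13 over untreated cells on each day; an asterisk marks a list called by camera with the preset correlation. All 24 mature adipocyte genes rose with differentiation, while at day 6 none of the lists had more than 3 members that rose after IL-13.

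**Figure D4:**
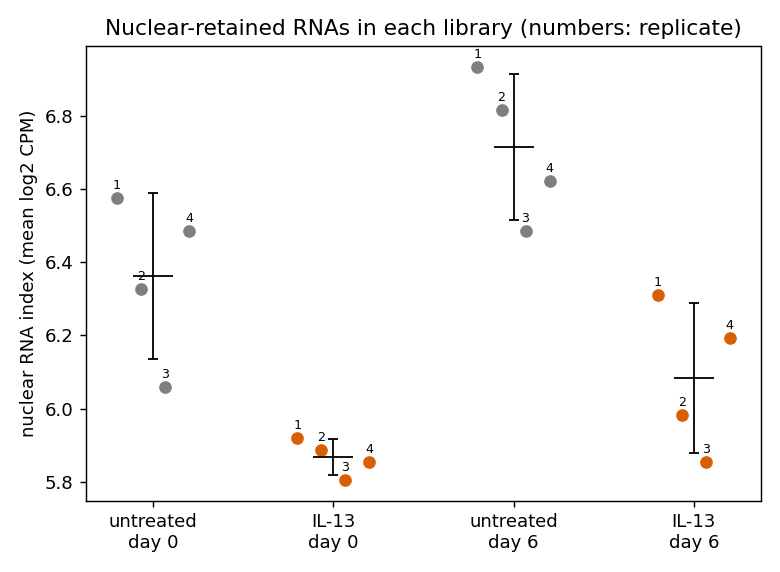
Nuclear RNA index (mean log2 CPM of 22 nuclear-retained and splicing-related RNAs) in each of the 16 libraries, scaled within each day, with the mean and SD of each group in black and the replicate number beside each point. On both days every IL-13 library lies below every untreated library of that day.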

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

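Tests chosen only after the result was seen were the fading of the nuclear RNAs between the days, the day 6 to day 0 ratios of the genes changed 2-fold or more at day 0, the share of calls kept with length and GC offsets, and every fit with the nuclear RNA index as a covariate. The nuclear RNA list itself was also written after the falls of Neat1 and Malat1 had been seen.

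Nuclear-retained RNAs and splicing factor transcripts were lower in IL-13 libraries on both days, with a median log2 fold change over 22 of them of -0.39 at day 0 and -0.54 at day 6. With offsets for transcript length and GC content the medians were -0.28 and -0.48, which argues against length and GC bias as the whole cause. The day 6 median was 1.40 times that of day 0, unlike a response that fades with the strong day 0 responses. Within groups the 22 RNAs went up and down together, with a mean pairwise correlation of 0.557 at day 0 and 0.715 at day 6 against 95th percentiles of 0.0975 and 0.0786 for 1000 random lists, so the amount of nuclear RNA may vary between libraries. IL-13 itself stays open as an untested biological cause, since every IL-13 library lay below every untreated one of its day.

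The small changes between IL-13 and untreated libraries may come in part from that variation. Slopes on the nuclear RNA index taken from the other day's libraries gave the observed sign for 96.5% of the genes called at day 6 (against 74.1% of those not called), 83.4% of those called at day 0 under 2-fold (against 63.9%) and 87.5% of the members of the lists called at day 6, a share that 30 of 576 orders of the libraries also reached. For genes changed 2-fold or more at day 0 the same sign test, chosen before, did not decide (75.4%, and 60.9% for those raised 4-fold or more), and the later test set their median fold change at day 6 against that at day 0. The ratio was 0.0782 (95% bootstrap interval 0.0484 to 0.0998) for the genes raised. This argues against the index difference as their cause, because that difference was at least as wide at day 6. For the genes lowered the ratio was 0.430 (0.358 to 0.512). There nuclear RNA and IL-13 cannot be told apart, because an IL-13 effect that lasts predicts no set ratio and could give this one. The ratios of the genes changed under 2-fold at day 0 were 0.501 for those raised and 0.435 for those lowered. Both intervals resample genes, which are not independent, and hold no spread between libraries. Choosing genes by a large day 0 change may itself lower the ratio. With length and GC offsets 73.8% of the day 0 calls were still called in the same direction. With the replicate block as well, 97.8% of the day 6 calls were, and without the block 774 of 809. Length and GC bias is thus unlikely to be the whole cause. Before the offsets, log2 fold changes correlated across genes with transcript length at -0.332 at day 0 and -0.317 at day 6 (Spearman). With GC content the correlations were 0.326 and 0.245.

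Genes raised 4-fold or more at day 0 lay near each other, as 27 of 88 were within 200 kb of another, where 0 of 10000 random sets of tested genes had as many (median 4, highest 19). Of 9 clusters 5 held genes of one name family, among them Serpina3c, Serpina3f, Serpina3g, Serpina3i and Serpina3n, and Ccl2, Ccl7, Ccl8 and Ccl11. These 5 clusters held 17 of the 27 genes. The random sets were not matched for such families, whose members lie side by side. They thus cannot show nearness beyond that of gene families. Reads shared between relatives are an unlikely cause for most, since the median share of 50-base stretches found in another gene's transcripts was 3.52%, although it exceeded 50% for Prl2c2, Prl2c3, Serpinb9g and Sprr2a2. The read length is not given in the sources used here. Joint regulation of neighbours by IL-13 may remain as a hypothesis.

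Of 230 groups of 4 libraries 6 held a library far from the other 3, where chance gives 11.5. The gap to the nearest library, as a share of the group's range, was 0.869 for Serpina3c in IL-13 library 2, 0.911 for Crispld2 in IL-13 library 4, 0.868 for Aif1l in untreated library 3, 0.966 for Clec2d in IL-13 library 3, and 0.853 for Socs1 and 0.899 for Cish in untreated library 4, all at day 0.

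The IL-13 effect differed between the days by the edgeR test of the difference for 52 of the named genes, 18 with a positive and 34 with a negative difference (day 6 minus day 0, log2). The most negative were Ccl11 -7.72, Serpinb1a -7.31, Serpina3g -6.59, Serpina3n -6.36, Myocd -5.61, Serpina3c -5.59, Hlf -4.34, Crispld2 -4.02, Ccl2 -3.64, Ccl7 -3.40, Aif1l -3.26, Pcolce2 -3.11, Tmem26 -3.03, Enpp3 -2.96, Daglb -2.68, Cish -2.62 and Aldh1a7 -2.48. Other negative differences were Col6a2 -1.86, Klf4 -1.83, Ptger4 -1.73, Plin1 -1.71, Socs1 -1.68, Jun -1.57, Col6a1 -1.56, Cd34 -1.53, Tgm2 -1.51, Il4ra -1.23, Fbn1 -1.09, Pnpla2 -0.85, Chac1 -0.62, Ptges -0.59, Pparg -0.53, Xbp1 -0.52 and Psat1 -0.33. The positive differences were Dock10 2.33, Rspo2 2.14, Adcyap1r1 2.08, Slc40a1 2.01, Ifit3 1.59, Fat4 1.53, Gas2 1.45, Mme 1.34, Slc1a3 1.33, Nrp2 1.09, Ifit2 0.76, Hsd17b7 0.74, Pdk4 0.72, Cebpa 0.70, Hmgcs1 0.56, Insig1 0.53, Agpat2 0.43 and Lpl 0.40.

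Other splits of the same libraries show how many genes are called when the groups are mixed. For IL-13 at day 0, 1 of 35 splits, the real one, gave as many as 5881 genes, and the highest other gave 0. At day 6 it was 1 of 35, with 809 genes and at most 617 in another split, the one that exchanged untreated library 4 and IL-13 library 1. If the replicate numbers pair the day 6 libraries, only 8 splits part all pairs, too few for a share under 0.05. Of these splits the real one gave 809 genes and the others 0. For the difference between the days it was 1 of 100, with 1061 genes and at most 947 in another. The split with 947 kept the real day 0 groups and mixed only the day 6 libraries. These draws mix libraries within each day, so they cannot show whether the IL-13 effect differs between the days. For day 6 against day 0 it was 1 of 35 in untreated cells (10590) and in IL-13 cells (10637). Any other split there gave 0. With pairing set aside, the real split called the most genes in each comparison, at a share under 0.05. With 35 splits that share cannot be below 1 in 35. Mixed groups hold any real difference inside them, which widens their spread. Their counts are thus not what chance alone would give. At day 6 the paired splits are too few to say. The splits cannot exclude a chance difference between cultures or in handling, because the labels do not say that the libraries of a group are separate cultures.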

How the results depend on the processing

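Alternatives chosen only after seeing the data were the nuclear RNA index as a covariate, the length and GC offsets, and the fits without the untreated libraries with most nuclear RNA. The planned pseudocount alternatives and the minimum of 0.1 were not run, because they were meant for tables without counts. The cause of the changes below was not tested.

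The test against a 1.5-fold change called fewer genes by construction, 485 at day 0, 0 at day 6 (209 at an unadjusted p under 0.05), 189 for the difference between the days, and 6318 and 6368 for the days in untreated and IL-13 cells. With the covariate the counts were 808 at day 0 (767 shared), 0 at day 6 and 2132 for the difference. At day 6 DESeq2 called 1470 genes, the replicate block 2812 (808 shared), the joint fit of 16 libraries 1405, the length and GC offsets 2277 (1491 higher and 786 lower), and these with the block 3764 (2531 and 1233). For the difference the block gave 1608 and a block within each day 1787. Without the untreated libraries with most nuclear RNA the counts were 3485, 2 and 545. Leaving out 1 library gave 4823 to 6593 genes at day 0, 60 to 2328 at day 6, 836 to 1269 for the difference, 10434 to 10786 for the days in untreated and 10413 to 10751 in IL-13 cells. At day 6 limma voom called 751. Libraries with the same replicate number correlated down to -0.369 at day 0, where the block gave 6518. With an estimated correlation 0, 0, 2, 3 and 3 of the 7, 4, 5, 12 and 11 lists were called. Fry called 14 lists at day 0, 0 at day 6 and 12 for the difference. For the days it called 24 in untreated and 24 in IL-13 cells.

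Of 1301 refits of 62 named genes at day 0, 1259 kept direction and call, 38 weakened, 1 strengthened and 3 reversed. At day 6 it was 515, 168, 26 and 16 of 725 refits of 33 genes, and for the difference 404 of 406 kept both and 2 weakened. For the days 1101 of 1102 refits in untreated and 194 of 196 in IL-13 cells kept both. The reversed log2 fold changes at day 0 were Stat6 -0.0819 with total count and -0.0571 with the covariate, and Fabp4 0.0359 with offsets. At day 6 with the covariate they were Il4ra -0.13, Ccl11 0.12, Cebpa -0.0330, Plin1 -0.0422, Ucp1 -0.23, Agpat2 -0.0170, Acaa2 -0.0231, Ndufb8 -0.0283, Tpi1 -0.12 and Pdia4 -0.0284. With total count they were Pparg -0.0320 and Fabp4 -0.00887, without untreated libraries 1 and 2 Ccl11 0.18 and Pparg -0.0291. Leaving out 1 library gave Ccl11 between -0.61 without IL-13 library 2 and 0.0337 without untreated library 1, with 0.0216 without IL-13 library 3. Between the days, offsets gave Pdgfra 0.10 in untreated and Il4ra 0.0381 in IL-13 cells. Counting depth limits genes near or under about 1 CPM.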

Other observations

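The groups below were fixed before the data were examined, and no test here was chosen after its result was seen. At day 0 members of several other lists passed the test in both directions, and camera called none of these lists. Fry called the immediate early list (fry adjusted p = 0.0474), the prostaglandin list (1.22e-04) and the glucocorticoid and cAMP list (6.19e-04). It did not call the glycolysis, fatty acid and triglyceride synthesis and cell cycle lists. In the immediate early list 2 of 15 genes rose, Jun (log2 fold change 1.45, SE 0.06) and Atf3, and 10 fell, with Nr4a1, an orphan nuclear receptor, at -1.57 (SE 0.15). The counts were the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.156). In the prostaglandin list 5 of 9 rose, with the receptor gene Ptger4 3.42-fold, the synthases Ptges 1.71-fold and Ptgs1 1.61-fold higher, and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.426). In the glucocorticoid and cAMP list 2 of 13 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.0816). The glycolysis list had 8 of 18 higher and 2 lower, the fatty acid and triglyceride synthesis list 3 of 18 and 3, and the cell cycle list 2 of 24 and 6 (1 and 4 adjusted over the list alone), with camera adjusted p = 0.203, 0.963 and 0.963.

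At day 0 camera called none of the 4 lists of markers of other cell types that it could test. Of 4 macrophage and leukocyte markers 1 rose, the receptor gene Csf1r from 1.65 ± 0.609 to 4.55 ± 0.833 CPM (n = 4), and 1 fell, Lyz2 (camera adjusted p = 0.821). The keratins Krt18 and Krt19 rose 3.99-fold and 2.72-fold, both tested mesothelial and epithelial markers. Of 5 muscle markers 0 rose and 1 fell, Acta1, and 0 of 4 endothelial markers passed in edgeR, with camera adjusted p = 0.320 and 0.862. Of 4 bone and cartilage genes Sox9 and Col2a1 rose and Spp1 and Runx2 fell (camera adjusted p = 0.940). These counts were the same adjusted over the list alone.

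At day 6 Zbtb16, a glucocorticoid target, was at -0.63 (SE 0.12) and Runx2, a bone lineage factor, at -0.71 (SE 0.13) on the log2 scale. Over all genes they alone passed among the 15 and 4 tested members of their lists, against 2 and 1 adjusted over the list alone (camera adjusted p = 0.203 and 0.700).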
